A study of Homo sapiens with 6 samples.

How the data were processed

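Total RNA was measured on 6 one-colour arrays of HaCaT cells, an immortalised human keratinocyte line. Per the labels, 3 samples received blue light and 3 were kept as controls without light, and all were harvested after 24 h. Per the labels' protocols, RNA was extracted with Trizol and biotin-labelled cRNA was prepared by the Affymetrix procedure. Per the submitters' processing notes, RMA was used (background correction, normalization and summary of probes). The deposited values are on a log2 scale, which was read from their range of 2.81 to 13.5, and they were not centred per gene. The software version, the probe set definition and any filter are not given in the sources used here. In 5 of the arrays the sorted deposited values were identical, and the array irradiated 1 differed from them by at most 0.00179, so the deposited log2 values had been quantile normalized after summarization. Irradiated 1 held 20265 distinct values and each other array 8122. No pair of arrays was identical.

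The table held 24733 rows, each an Entrez-numbered probe set. A probe table paired 23934 rows with 1 gene symbol, updated by Entrez number through an annotation of GRCh38.p14, and left 799 rows unnamed here. A symbol stood on more than 1 row in 3 cases, and the row with the highest mean over the 6 arrays then stood for the gene in gene lists and named genes. For arrays the number of samples limits the precision, and the signal over background was not analysed here. The p-values of single rows measure the spread between the samples of 3 plates.

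The series design puts irradiated and control cells on each of 3 plates to exclude a plate effect, so plate was a fixed block. The labels give the plate of every sample, which pairs the samples. Deviations from the group means correlated across rows by 0.0411 within plate 1, 0.310 within plate 2 and 0.255 within plate 3, against −0.287 to 0.0741 for arrays of different plates. The consensus within-plate correlation was 0.140.

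The deposited log2 values were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, irradiated against control, with Benjamini-Hochberg adjustment over all 24733 rows and a threshold of 0.05. No row was filtered out. The fit had 2 residual and 3.22 prior degrees of freedom. Gene lists, 25 in number, were tested with limma's camera (preset inter-gene correlation 0.01), with adjustment over the lists. In this form camera compares a list's genes with all other genes. Its p-values thus rest on the spread between genes and do not measure how a list's mean varies between plates. Camera with an estimated correlation and fry stand beside it. The lists, the rules and the alternatives listed here, apart from those named as added later, were fixed before the data were examined.

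Named genes were chosen by rule. Where fewer than 10 genes passed the adjusted threshold, which was the case, the rule took the 10 largest positive and the 10 largest negative differences among genes with an unadjusted p under 0.01 and 1 direction in all 3 plates. This pool held 138 higher and 113 lower genes. The rule also took up to 4 members of each list with the smallest unadjusted p, and 23 genes fixed in advance.

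The alternatives were no plate block, plate as a random effect, median centring, quantile normalization, leaving out rows under the 30th percentile of mean level, a variance trend with robust hyperparameters, averaging rows of a gene, other thresholds including a fold of at least 1.5, other set tests, and leaving out each plate. With plate as a block, leaving out 1 array is the same as leaving out its plate. Changes in list membership and 3 further gene lists were added after the data were seen.

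The limma fit was tested on simulated data of 24733 rows with 200 changed rows in each of 20 runs, with row variances drawn from the fitted variance model. The share of changed rows recovered was 8.8% at a log2 change of 0.5, 86.7% at 1, 96.2% at 1.5 and 99% at 2, with 6.95 false calls per run. These shares hold for 200 changed rows, and because the adjustment becomes stricter with fewer changed rows they do not apply to a few changed genes. The list test was tested on 23931 simulated genes without correlation between them. Shifts of 0.28 in the list of AHR targets and 0.12 in that of NRF2 targets were called in 100% of the 20 runs, and 0 of the 23 unshifted lists were called. Both sizes were those seen in these data, and every member was shifted alike. The estimated correlation within real lists reached 0.389, for histone genes. The runs therefore do not show how often the list test makes false calls in real data.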

Results

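RNA levels were measured in HaCaT cells, an immortalised human keratinocyte line that grows without a feeder layer and is widely used as a model of the epidermis. Cells in 3 plates were exposed for 7.5 min to blue light from diodes with a peak wavelength of 453 nm at 23 mW/cm2, a dose of 10.35 J/cm2, from a distance of 55 mm. Control cells on the same 3 plates received no light. Both groups were harvested at 24 h, which gave 3 irradiated and 3 control arrays, 1 of each per plate. Every array gave a level for 24733 rows, with a median log2 level of 4.23 and a range of 2.81 to 13.5. Correlations between arrays over all rows lay between 0.992 and 0.997. The first principal component held 36.7% of the variance and had irradiated 3 at one end (24.4) and control 2 at the other (−22.3), while the remaining arrays of both groups lay between them.

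The comparison of irradiated with control cells asked which transcripts differed 24 h after a single dose of blue light, in a study of how this light acts on keratinocyte proliferation. Target genes of the aryl hydrocarbon receptor (AHR), a ligand-activated transcription factor, were higher as a group after blue light, by 0.28 on the log2 scale over 15 measured genes (camera adjusted p = 8.3e-07). This call was lost in camera's other form (adjusted p = 0.428 with an estimated correlation), and without CYP1A1 and CYP1B1 the mean was 0.15 over the other 13 genes, a comparison chosen after seeing the data. Its best known target, CYP1A1, which encodes a xenobiotic-oxidising cytochrome P450, was 2.80-fold higher. Its mean log2 level was 4.48 ± 0.34 in controls and 5.96 ± 0.62 after light (SD, n = 3 arrays per group), and it was higher on all 3 plates. The level in controls lay near the median row level of 4.22. Targets of NRF2, the transcription factor of the oxidative stress response, were higher by 0.12 on average over 25 genes, a call that was lost in the same way (adjusted p = 0.428 with an estimated correlation). No single gene passed limma's test over all rows.

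With limma and Benjamini-Hochberg adjustment, 0 rows were higher and 0 were lower at an adjusted p under 0.05, and the smallest adjusted p was 0.890. At an unadjusted p under 0.05 there were 1363 rows, 736 higher and 627 lower, where chance alone gives 1237. At an unadjusted p under 0.01 there were 260 rows, against 247 by chance. The same direction on all 3 plates was seen in 25.4% of rows, against 25% by chance. The light differences of 2 plates correlated across rows by −0.0824 for plates 1 and 2, −0.00923 for plates 1 and 3 and 0.126 for plates 2 and 3, and rows are not independent replicates. The median standard error of a log2 difference was 0.0797. CYP1A1 passed under 1 alternative variance model, with a limma adjusted p of 0.0270, where its limma adjusted p ranged up to 1 under the other settings.

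Among single genes, the rule for named genes took 10 with higher and 10 with lower levels after light, none of which passed the adjusted threshold (limma adjusted p = 0.890 for each). CYP1A1 headed the first set with a log2 difference of 1.48 (SE 0.13), and its differences were 1.30, 1.30 and 1.84 on plates 1, 2 and 3. CYP1B1, a related cytochrome P450 that also is an AHR target, was 1.63-fold higher, with a mean log2 level of 7.40 in controls and 8.10 after light. Its log2 differences were 0.30, 0.76 and 1.06 on plates 1 to 3. The pseudogene NMRAL2P was 1.80-fold higher (log2 difference 0.85, SE 0.16). KRT8, a keratin of simple epithelia, was 1.71-fold higher (0.78, SE 0.13), while its usual partner KRT18 differed by −0.14, and KRT8 has many processed pseudogenes that can share its probes. ADGRE2, an adhesion G protein-coupled receptor, was 1.66-fold higher (0.73, SE 0.07). The others were NSUN5P1 with a log2 difference of 0.72, SPECC1L with 0.71, ZNF736 with 0.69, and the non-coding GNB1-DT and PRR7-AS1 with 0.65 and 0.64.

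On the lower side, TNFSF10, which encodes the death receptor ligand TRAIL, was 1.60-fold lower, with a log2 difference of −0.68 (SE 0.17). METRN, which encodes the secreted factor meteorin, was 1.76-fold lower (−0.82, SE 0.11). The small RNAs RNU6-59P and SNORA14A had the largest negative differences, −1.12 (SE 0.19) and −0.95 (SE 0.15). KRTAP19-5, of a hair keratin-associated family, differed by −0.87 and the mast cell tryptase gene TPSD1 by −0.82. TMEM278, FAM72D, FOXD4L3 and CLEC18C differed by −0.72, −0.71, −0.66 and −0.60. RNU6-59P, SNORA14A, NSUN5P1, FAM72D, FOXD4L3 and CLEC18C belong to families of near-identical copies, so their levels are uncertain.

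**Figure D1:**
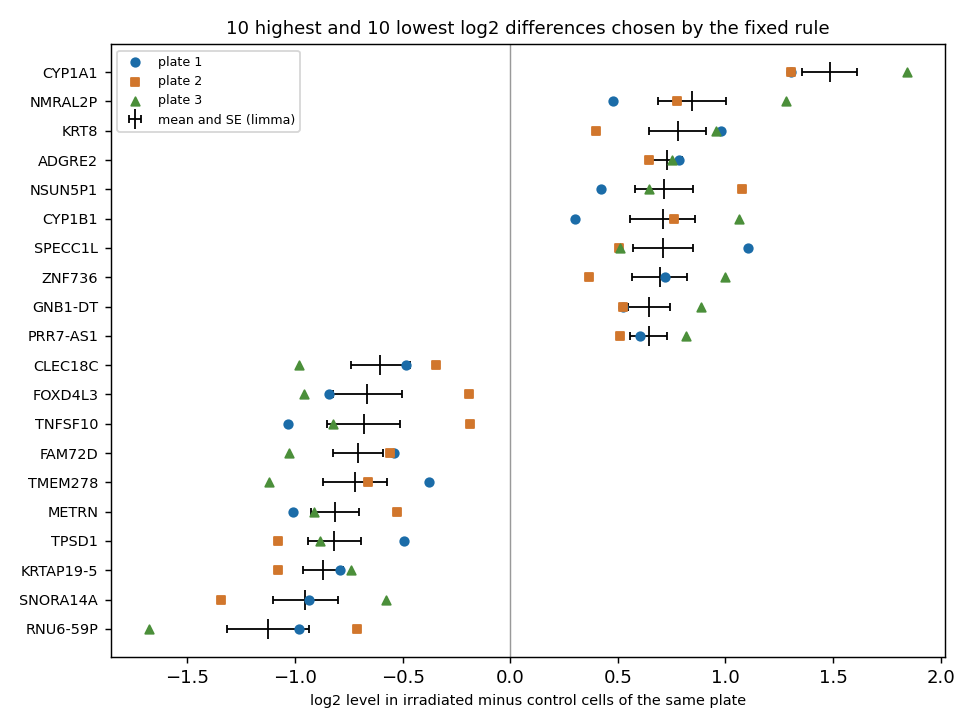
Log2 level in irradiated minus control cells of the same plate (horizontal axis) for the 20 genes chosen by the rule, with plates 1, 2 and 3 as circles, squares and triangles and the limma mean with its standard error as a bar. CYP1A1 lies highest at 1.48 and RNU6-59P lowest at −1.12, and every gene has 1 direction on all 3 plates, which the rule required.

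AHR targets were the list that stood out most. Of its 15 measured genes, 13 were higher and 2 lower after light, and the list's shift had a camera adjusted p of 8.3e-07 over the 25 lists. With camera's other form, the adjusted p = 0.428 with an estimated correlation, a form that has only the 2 residual degrees of freedom of the fit. The mean shift was 0.29 on plate 1, 0.20 on plate 2 and 0.34 on plate 3, and the median member differed by 0.16. Adjusted over the list alone, 5 genes passed limma's test, all higher, where 0 passed over all rows. These were CYP1A1, CYP1B1, NQO1 (a quinone reductase, from 9.96 to 10.35, log2 difference 0.40, SE 0.08), EREG (the growth factor epiregulin, 0.34, SE 0.07) and FLG (the barrier protein filaggrin, 0.32, SE 0.08). EREG also stands in the growth factor list and FLG in the differentiation list. Of the other members, the amino acid transporter gene SLC7A5 differed by 0.18 and TIPARP by 0.10. AHRR, which encodes the receptor's repressor, differed by 0.07 with a wide spread (SE 0.23), from −0.54 on plate 2 to 0.69 on plate 1.

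**Figure D2:**
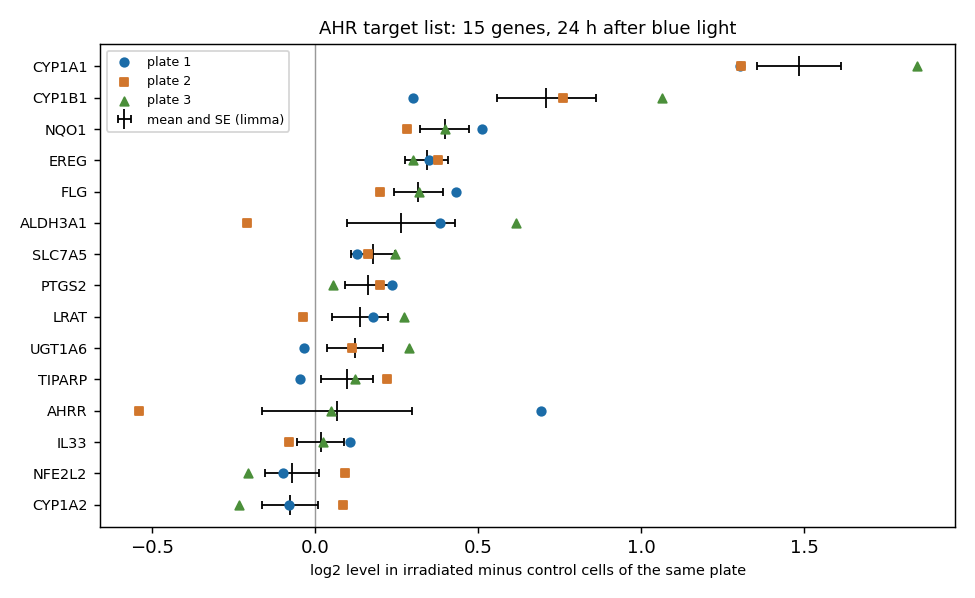
Log2 level in irradiated minus control cells of the same plate (horizontal axis) for the 15 measured AHR target genes, with plates 1, 2 and 3 as circles, squares and triangles and the limma mean with its standard error as a bar. CYP1A1 (1.48) and CYP1B1 (0.71) lie farthest to the right, and AHRR has the widest spread between plates.

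NRF2 targets were higher in 20 of 25 measured genes and lower in 5, with a camera adjusted p of 2.9e-05 over the lists (adjusted p = 0.428 with an estimated correlation). The mean shift was 0.10, 0.15 and 0.12 on plates 1, 2 and 3. No member passed limma's test adjusted over the list alone (0 genes) or over all rows (0 genes). By unadjusted p, NQO1, shared with the AHR list, came first, followed by ABCC3, an efflux transporter gene (0.34, SE 0.09), HMOX1, which encodes the haem-degrading enzyme haem oxygenase (0.27, SE 0.07), and AKR1C3, an aldo-keto reductase gene (0.42, SE 0.12). FTL, which encodes the ferritin light chain, differed by 0.34 (SE 0.11). AKR1C3 had low mean log2 levels, 3.50 in controls and 3.92 after light, below the median row level of 4.22. Its differences were 0.48, 0.67 and 0.10 on plates 1, 2 and 3. The mean log2 level of HMOX1 was 4.51 in controls and 4.79 after light, near the median row level.

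Growth factor and immediate early genes had a small mean shift of 0.08 over 26 genes, with 15 higher and 11 lower. Camera's adjusted p was 0.0333, and the adjusted p = 0.898 with an estimated correlation. Without plate 2 the mean shift was 0.0697 and its camera adjusted p 0.269, so the call was lost while most of the shift stayed, and the means on plates 1, 2 and 3 were 0.05, 0.11 and 0.08. Without the plate block, the shift of 0.0845 had an adjusted p of 0.561, and over all settings the adjusted p ranged from 0.00768 to 0.898. The members went both ways: adjusted over the list alone, FOSL1 and EREG passed limma's test as higher and FOS as lower, where 0 passed over all rows. FOSL1 and FOS both encode subunits of the AP-1 transcription factor. FOSL1 differed by 0.56 (SE 0.10) and FOS by −0.40 (SE 0.07), while SPRY4, which encodes a feedback inhibitor of growth factor signalling, differed by 0.30. The mean log2 level of FOS was 4.65 in controls and 4.25 after light, near the median row level of 4.22.

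Cell cycle lists were not called. The 34 genes of G2/M and mitosis had a mean shift of −0.05, with 24 lower and 10 higher (camera adjusted p = 0.155), and the 29 genes of G1/S and DNA replication one of 0.03 (0.402). The proliferation marker MKI67 differed by −0.02 (SE 0.07), CCNB1, the mitotic cyclin B1 gene, by −0.11 (SE 0.07), PCNA by −0.01 and the cell cycle inhibitor gene CDKN1A by 0.11. Replication-dependent histone genes, whose near-identical copies are hard to tell apart, had a mean of −0.04 over 28 genes (0.402), with 0.08, 0.03 and −0.23 on plates 1 to 3. Without plate 1 their shift was −0.102 with an adjusted p of 0.0479. Their estimated correlation was 0.389, well above the preset 0.01, so that p may be too small. With the estimated correlation and all plates, camera's adjusted p was 0.931. The 23 p53 targets had a mean of 0.02 (0.765), with PLK3 at 0.39 and PLK2, its relative, at −0.17.

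Keratinocyte differentiation genes had a mean shift of −0.03 over 39 genes (camera adjusted p = 0.765). Within this list IVL, which encodes the cornified envelope protein involucrin, differed by −0.42 (SE 0.11) and the protease gene KLK7 by −0.26, while FLG differed by 0.32 and GRHL3, a transcription factor gene of barrier formation, by 0.27. The suprabasal keratins KRT1 and KRT10 differed by −0.42 (SE 0.19) and −0.47 (SE 0.24), mostly through plate 1. KRT1 differed by −1.0, −0.21 and −0.04 on plates 1, 2 and 3, and KRT10 by −1.21, −0.29 and 0.08. The 18 basal keratinocyte genes had a mean of −0.0011 (0.929), and the basal keratins KRT5 and KRT14 differed by −0.08 and −0.01.

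Inflammatory cytokine and NF-kB target genes moved in both directions, with a mean of 0.01 over 26 genes (camera adjusted p = 0.765). Adjusted over the list alone, IL1A passed limma's test as higher and the chemokine genes CXCL8 and CCL2 as lower, where 0 passed over all rows. IL1A, which encodes interleukin 1 alpha, differed by 0.41 (SE 0.07), CXCL8 by −0.47 (SE 0.07) and CCL2 by −0.54 (SE 0.10). TNFAIP3, which encodes an inhibitor of NF-kB signalling, differed by 0.27 and IL6 by −0.06. IL6 had low mean log2 levels, 3.79 in controls and 3.73 after light, below the median row level of 4.22. The 28 interferon-stimulated genes had a mean of 0.02 (0.791).

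Steroid and retinoid metabolism genes had a mean shift of 0.07 over 42 genes (camera adjusted p = 0.372), where adjusted over the list alone 1 gene passed limma's test, CYP1A1, shared with the AHR list, and 0 passed over all rows. The unfolded protein and ATF4 response list had a mean of 0.04 over 28 genes (0.338), with the stress genes TRIB3 at 0.33, CHAC1 at 0.31 and DDIT3 at 0.14. Circadian clock genes had a mean of 0.05 over 18 genes (0.338), in which PER3 differed by 0.45 (SE 0.09) and PER1 by −0.01. Opsins and flavoprotein light absorbers had a mean of 0.03 over 22 genes (0.402), with NOS1 at 0.42 and XDH at 0.26. Cholesterol biosynthesis genes had a mean of 0.01 over 18 genes (0.765), with CYP51A1 at 0.24, TM7SF2 at −0.26 and HMGCS1 at 0.07. PPAR and fatty acid metabolism genes had a mean of −0.0046 over 21 genes (0.946), with the lipid droplet gene PLIN2 at 0.31 and the beta-oxidation gene HADHB at −0.34.

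Nuclear-encoded respiratory chain genes had a mean of −0.03 over 39 genes (camera adjusted p = 0.293), with −0.13 on plate 2. Without plate 1 the shift was −0.0631 with an adjusted p of 0.0491. The estimated correlation of this list was 0.212, well above the preset 0.01, so that p may be too small. With the estimated correlation and all plates, camera's adjusted p was 0.898. Cytosolic ribosomal protein genes had a mean of −0.03 over 38 genes (0.402), hypoxia and glycolysis genes −0.02 over 25 (0.765), heat shock response genes −0.01 over 19 (0.946), and TGF-beta and matrix genes −0.0060 over 27 (0.929). In these lists ADM, which encodes the peptide adrenomedullin, differed by −0.27 and TNC, which encodes the matrix protein tenascin C, by −0.35 (SE 0.07). Markers of other cell types were not called either: fibroblast markers had a mean of −0.03 over 16 genes (0.747), melanocyte markers −0.01 over 12 (0.946), and leukocyte and endothelial markers 0.0028 over 16 (0.946). The mean and camera's direction had opposite signs for basal keratinocyte, PPAR and TGF-beta genes, and the median and mean for interferon-stimulated, melanocyte and TGF-beta genes. The common reference genes GAPDH and ACTB differed by −0.22 (SE 0.15) and 0.11 (SE 0.14).

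Of the 25 lists, 3 were called higher and 0 lower with camera's preset correlation, and 0 with an estimated correlation. Fry, which asks whether a list's genes move one way without comparing them with other genes, called 0 lists. Its mixed test, which asks whether genes of a list move in either direction, called 7: opsins and flavoproteins (adjusted p = 0.00158), NRF2 targets (0.0262), inflammatory genes (0.0297), and AHR targets, growth factor, PPAR and TGF-beta genes (0.0293 each). In the opsin and flavoprotein list, 0 of 22 genes passed limma's test adjusted over the list alone. Only NOS1 and XDH had an unadjusted limma p under 0.05, and the smallest such p of an opsin was 0.373, for OPN4. The directional fry adjusted p of this list was 0.547. The mixed test was not run on other groupings of the arrays.

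**Figure D3:**
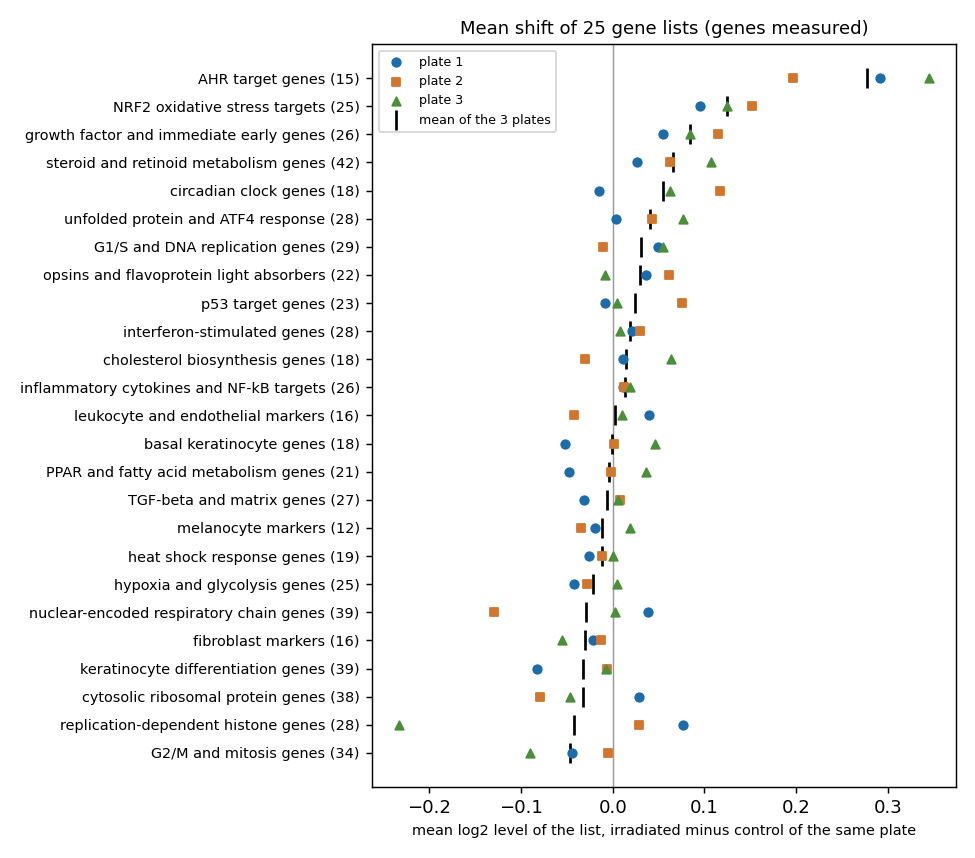
Mean over each of 25 gene lists of the log2 level in irradiated minus control cells of the same plate (horizontal axis), with plates 1, 2 and 3 as circles, squares and triangles, a bar for the mean of the 3 plates and the number of genes measured after each name. AHR targets (0.28) and NRF2 targets (0.12) have the highest means, and both are above 0 on all 3 plates. So are the growth factor, inflammatory, interferon, ATF4 and steroid lists, while the G2/M, differentiation and fibroblast lists are below 0 on all 3.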

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

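The shifts of AHR targets and NRF2 targets kept their direction and their call without each plate in turn (highest camera adjusted p 0.000204 and 0.00576), with no plate block, with plate as a random effect, without dim rows and with a variance trend. With an estimated correlation (0.277 and 0.124, adjusted p = 0.428 each) and by fry (adjusted p = 0.220 each) neither passed, the first because that form has only 2 residual degrees of freedom, while for fry the cause was not tested. The growth factor shift was the least stable: it was no longer called with no plate block (0.0845, adjusted p 0.561), with plate as a random effect (0.883), without dim rows (0.0564), with an estimated correlation (0.898), by fry (0.622) or, chosen after seeing the data, without members shared with the other called lists (mean 0.0742, adjusted p 0.128), and the cause was not tested. Counts of rows past the adjusted threshold were 0 higher and 0 lower under every other setting of the limma fit, no block included, except that a variance trend with robust hyperparameters gave 1 higher row, CYP1A1, with an adjusted p of 0.0270 against 0.890 as reported and up to 1 elsewhere. An unadjusted p under 0.05 with a fold of at least 1.5 gave 16 higher and 19 lower rows. Leaving out 1 plate at a time, which is also leaving out any 1 of its arrays, gave these ranges for values near 0 that changed sign or side: respiratory chain −0.0631 (adjusted p 0.0491, without plate 1) to 0.0208, histones −0.102 (0.0479, without plate 1) to 0.0528, growth factor genes 0.0697 (0.269, without plate 2) to 0.0994, basal keratinocyte genes −0.0249 to 0.0242, PPAR genes −0.0248 to 0.0172, TGF-beta genes −0.0128 to 0.00681, leukocyte and endothelial markers −0.0158 to 0.0252, p53 targets −0.00182 to 0.0399 and cholesterol genes −0.00961 to 0.0374. Among single genes, none past the threshold, the ranges were −0.245 to 0.370 for AHRR, −0.0397 to 0.0283 for PCNA, −0.0236 to 0.306 for ACTB, −0.00773 to 0.122 for FCER1G, −0.0235 to 0.125 for SLC45A2, −0.0304 to 0.00521 for PER1, −0.0772 to 0.0606 for KRT14 and −0.0573 to 0.00130 for MKI67. Repeated quantile normalization and median centring moved log2 values by at most 0.00149 and 0.000814, and averaging rows touched 3 symbols, so these settings could test nothing. The block changed no other call.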

Other observations

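The tests of other groupings of the arrays, of single plates for AHR and NRF2 targets, of RNA from other cell types and of the receptor complex were chosen only after the result was seen, and the 3 further gene lists, the genes with the largest plate differences and the gene classes were chosen after the data were seen. The bounds of 2 standard errors for the added lists and for the markers of other cell types, and the reading of the growth factor shift without plate 2, were also set after the values were seen; the first rule for the markers, a largest difference below the AHR list's mean, would have counted against RNA from other cell types.

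Some transcripts differed more between the plates than between irradiated and control cells. SERPINB4, a serpin gene of squamous epithelium, had mean log2 levels of 5.50, 3.17 and 4.82 on plates 1, 2 and 3, and PI3, which encodes the elastase inhibitor elafin, had 6.98, 5.19 and 7.17. CEACAM5, a cell adhesion gene, had 7.33, 5.43 and 6.38. The suprabasal keratin gene KRT10 stood at 9.74 on plate 1 against 7.58 and 7.74, and KRT1 at 5.28 against 3.44 and 3.87. On plate 1 KRT10 and KRT1 differed after light by −1.21 and −1.0, on plate 2 by −0.29 and −0.21, and on plate 3 by 0.08 and −0.04. By contrast KRT14, a basal keratin gene, stood at 12.3, 12.1 and 12.2. CYP1A1 also varied, with 5.17, 4.78 and 5.72. In limma's test of the plate term 0 rows passed an adjusted p of 0.05. An unadjusted p under 0.05 was found for 2356 rows, where chance alone gives 1237, against 1363 rows for the light term.

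Lists next to the called ones in function were not called. The 29 measured phase II conjugation enzymes had a mean shift of 0.02 (SE between members 0.02), and camera's p adjusted over the 3 added lists was 0.647. For 20 genes of tryptophan and kynurenine metabolism, which makes AHR ligands, the mean was −0.01 (SE 0.03, adjusted p 0.647), with AFMID at 0.27, KMO at −0.29 and HAAO at −0.23. The 11 genes of the AHR receptor complex had a mean of −0.02 (SE 0.04, adjusted p 0.647), and AHR itself differed by −0.04 at a mean log2 level of 10.7. Many phase II and kynurenine genes lay below the median row level of 4.22, such as UGT2B15 (2.94) and IDO1 (3.20). Members with such low levels could hold the means of these lists near 0. For each of the 3 added lists the mean plus 2 standard errors, 0.0584, 0.0446 and 0.0588, lay below the NRF2 list's mean of 0.124. For the receptor complex, where only ARNT2 (3.58) lay below the median row level, a rise as large as that of the NRF2 targets was thus not borne out in these arrays. For the phase II and kynurenine lists the bounds cannot decide this, because dim members could pull the means towards 0. The standard errors of all 3 added lists treat genes as replicates and leave out the spread between plates. The bounds therefore do not extend to other cultures. By gene class, an unadjusted p under 0.05 was found for 7.35% of 313 snoRNA rows and 7.16% of 796 transcribed pseudogene rows, 5.69% of 17753 protein-coding rows, 5.55% of 1082 miRNA rows and 3.98% of 3564 lncRNA rows, and the differences between classes were not tested.

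AHR targets were higher after light with camera's preset correlation, a call lost in other set tests (adjusted p = 0.428 with an estimated correlation and 0.220 by fry). Within the preset form, the tables argue against a shift carried by CYP1A1 and CYP1B1 alone or by 1 plate. Without CYP1A1 and CYP1B1, the mean dropped from 0.277 to 0.151 over the other 13 genes, with an unadjusted camera p of 2.3e-05. The highest camera adjusted p without a plate was 0.000204. NQO1, EREG and FLG, which also passed limma's test over the list alone, stayed among the 13 genes. Whether a few strong genes carried the shift was therefore not tested. The labels name HaCaT cells only and no other cell type. The markers by themselves could not decide on RNA from other cell types. No marker list was called, and 8 marker genes lay above the median level. The largest difference among these, CD68, was 0.159, and plus 2 standard errors it reached 0.311, above the AHR list's 0.277. For MC1R, which differed by −0.06 with a wide spread (SE 0.20), the same bound was 0.343. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05, with an absolute mean of 0.277 in the real split (1 split as large, itself) and at most 0.260 in the others, 2 of which also called the list (adjusted p of 0.0193 and 0.000328, against 0.00054 in the real split without the block). Both of these set whole plates against each other, and every other split keeps part of the light contrast. The 4 splits with 1 array of each plate in each group are too few as well, with 0.277 (1 split as large, itself) against at most 0.147 in the others. The light itself, which the design names, stays among the open explanations.

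NRF2 targets were higher by a smaller amount with the preset correlation (adjusted p = 0.428 with an estimated correlation and 0.220 by fry). In the preset form, a single plate did not account for it, as the highest adjusted p without a plate was 0.00576. Of the measured genes only NQO1 is shared with the other called lists, so leaving it out could hardly end the call. Without NQO1 the 24 remaining genes had a mean of 0.11 with an unadjusted camera p of 1.6e-05. The 10 splits are too few for a share under 0.05 (0.124 in the real split, at most 0.0778 in the others, 1 split as large), as are the 4 splits within plates (0.124 against at most 0.0606, 1 split as large). The light stays open as an explanation here too.

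For growth factor and immediate early genes (adjusted p = 0.898 with an estimated correlation), only EREG of the measured genes is shared with the other called lists. Without EREG the mean was 0.0742 (unadjusted camera p of 0.0154, adjusted 0.128), so this gene alone did not account for the whole shift. A single plate stays open. Without plate 2 the adjusted p was 0.269, but the mean was still 0.0697, and a lost p alone does not show that this plate carried the shift. Of the 10 splits, too few for a share under 0.05, 7 had an absolute mean as large as the real 0.0845, with up to 0.335 in the others. The 6 others that reached it part only 1 plate between the groups and set the other 2 plates against each other. Of the 4 splits within plates, also too few, 1 had (0.0845 against at most 0.0480). For rows past the adjusted threshold, the real split had 0 and the others at most 0, so all 10 splits and all 4 within plates had as many, and neither number can give a share under 0.05. For lists called without the block, the real split had 2 and the others up to 7, with 7 of 10 splits at least as high, and with the block 3 against at most 1, with 1 of 4 as high. Without the block, the 6 splits that set whole plates against each other called 4 to 7 lists, and the 3 others that part all 3 plates called 0 to 1, so the high counts followed differences between plates.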
